A study of Mus musculus with 103 samples.

How the data were processed

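The series held 103 arrays of mouse RNA on 1 Affymetrix array design, in 4 sets: 58 arrays of universal RNA, 16 of tissue RNA, 18 of sorted T and B cells and 11 of sorted RAW267 cells. Groups, inputs, cell numbers and replicate numbers were taken from the labels. Per the labels, one-cycle, two-cycle and RiboAmp HS arrays were hybridised with cRNA and Ovation and BIIB arrays with cDNA.

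The deposited values were MAS5 signal intensities on a linear scale, 1 value per probe set and array, per the submitters' processing notes. The MAS5 version and its scaling and background settings were not given in the sources used here. From the values themselves, the mean of each array without the top and bottom 2% of probe sets lay between 2500.23 and 2502.45, so every array had been scaled to 1 level, and the median signal lay between 228 and 1656. A MAS5 signal is scaled per array and not matched in distribution, so medians differ between arrays. No scanner files or detection calls were used here, and the number of arrays limits the precision of each value. All columns were matched to a sample.

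Each array was scaled to the common trimmed mean of 2501 and log2(signal + 125) was taken, a pseudocount of 5% of that mean, so changes of dim probe sets are understated. Probe sets with a mean signal under 500 (20% of the common mean) over the arrays of a fit were left out of its test, and so were the 64 control probe sets, which left 22626 that could be tested. A gene dim in one group passes this filter only if it is bright in another, so the members of a list that are measured are partly chosen by their change. Probe sets were named from the platform annotation given with the data: 21084 were listed, 20393 with 1 gene symbol and 691 with several, and 1606 were unlisted, the 64 controls among them. No gene was named from a probe set with several symbols. Symbols were checked by Entrez number against a RefSeq gene table of assembly GRCm38.p6, used for names alone, where 20364 matched and 0 changed.

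The 29 comparisons were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). A probe set was called with a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Each BIIB input was tested against 5 ng and each protocol against one-cycle in a fit of the groups compared. Each kit at 50 pg was tested against 500 ng in a fit of its 10 arrays over 5 inputs, which share 1 spread. The median SD between replicates was 0.135 at 500 ng and 1.41 at 50 pg with Ovation, and 0.099 with one-cycle. A shared spread understates the SE of the noisier group where it holds few of the arrays. So for the kits at 50 pg, against 500 ng, one-cycle or BIIB, p can be too small and calls too many. Each tissue was tested against the mean of the other 7 in a fit of 16 arrays with the protocol as a covariate. Unmixed B cells were tested against unmixed T cells in a fit of the 12 arrays of 100 cells. RAW267 arrays were fitted with a slope on log10 cell number, given as the change from 50 to 10000 cells. Comparisons that share control arrays share their chance values, so no overlap or correlation between them is given. The change from 5 ng to 50 pg was compared between kits and BIIB by an interaction term.

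Gene lists were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes, while which list goes with which comparison was chosen after. There were 22 lists: markers of T, B, NK, myeloid, erythroid and plasma cells, of macrophages and of the 8 tissues, mitotic, immediate early and heat shock, and reference genes, ribosomal proteins, oxidative phosphorylation, replication-dependent histones and proteasome subunits. The oxidative phosphorylation list was drawn by symbol and so also holds assembly factors and tissue isoforms. The first count of a list is over all probe sets tested, and the second is adjusted over the list alone. List shifts were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Of 244 list tests 129 passed with the preset one and 58 with the estimated one, all 58 among the 129, and of the 58, 54 also passed without the filter, and the text gives adjusted p with the estimated correlation.

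Named genes were members of the lists that fit a comparison and, among calls with 1 symbol whose arrays did not overlap between groups, the 5 with the largest change each way. The number was 10 for B against T cells and 3 per tissue, and the RAW267 trend had no rule on overlap. A gene with several probe sets was represented by the brightest, and the others were checked. No gene is named here whose other probe sets were called the opposite way.

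The share of B cells in an array was the median, over T and B cell genes at least 2-fold apart between the unmixed 500-cell arrays, of the distance of its signal from the T cell end over the distance between the ends. Its correlation with the nominal share was tested with 100000 permutations. Replicates were compared by Pearson's r and by the median SD of log2 signal, and no pair of columns was identical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

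The scheme was tested on simulated arrays with known changes in 200 genes (log2 1.5 or 3, 100 genes each). After this recovered none in several comparisons, it was tested with 300 genes (1.5, 3 or 6). The noise was normal, with 1 spread per probe set from the fit of the real arrays. Unequal spread between inputs, correlation between genes and shifts of whole arrays were left out, so false calls from these were not tested. The setups differ in both the number and the sizes of the changes. For BIIB at 10 pg against 5 ng (11262 and 11253 probe sets), 1 and 18% of the 2 sizes were recovered in the first setup and 2, 32 and 67% of the 3 sizes in the second. For BIIB at 50 pg against 5 ng (11508 and 11441) it was 15 and 57%, then 22, 67 and 93%. For 50 pg against 500 ng the first setup recovered 0% with each kit, and the second 1, 34 and 55% with two-cycle (15046), 1, 16 and 48% with Ovation (12291) and 0, 20 and 57% with RiboAmp HS (13790). For B against T cells (17665 and 17633) it was 0 and 0%, then 1, 0 and 18%, and for the RAW267 trend (11391 and 11405) 27 and 60%, then 24, 69 and 76%. For lung (13555 and 13561) it was 53 and 84%, then 57, 84 and 95%. Simulated mixtures (12 arrays, 45 genes) gave shares with r = 0.994 and a root mean square difference of 3.91 points.

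Alternatives were pseudocounts of 2.5 and 10%, no filter and a filter at 40%, quantile normalization of the arrays of a fit, the replicate number as a block, all BIIB arrays of universal RNA in 1 fit, and leaving out each array in turn. Where an array left out leaves 1 in its group, that array is assumed to vary like the other groups. Replicate numbers were the only link between groups in the labels. They paired the arrays in 1 comparison, BIIB at 500 pg against 5 ng, where the deviations of arrays with the same number correlated at 0.13 to 0.25 in every pair. Added after the data were seen were a technical block and subsets by replicates 1 and 2 against 3 and 4, replicates 1 and 2 at 100 pg as 1 array, the RAW267 trend without 50 cells, 10 pg against 5 ng without liver and testis transcripts, and gene lists without the filter.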

Results

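Expression was measured on 103 Affymetrix mouse arrays of 22690 probe sets each, in a series on how amplification and labelling protocols profile picogram amounts of RNA or small numbers of sorted cells. Universal mouse RNA, a commercial pool of total RNA, was on 58 arrays. It was labelled from 1 ug by the Affymetrix one-cycle protocol (4 arrays). The Affymetrix two-cycle, Nugen Ovation and Arcturus RiboAmp HS kits labelled it from 500, 50 and 5 ng and from 500 and 50 pg (2 arrays per kit and input). The protocol developed at Biogen Idec, called BIIB in the labels, labelled it from 5 and 1 ng and from 500, 100, 50 and 10 pg (4 arrays per input). Total RNA of 8 tissues was on 16 arrays, 1 per tissue by one-cycle from 1 ug and 1 by BIIB from 500 pg. T and B lymphocytes sorted from the spleen of a single mouse were mixed in 6 ratios and labelled by BIIB, with 2 arrays per ratio at 100 cells and 1 at 500 cells. A cultured line given as RAW267 was sorted into samples of 50 to 10000 cells (11 arrays, BIIB). No label said that replicates came from separate preparations, cultures or animals, so p-values measured only the spread between these arrays, which may be technical. The number of arrays limits the precision. Changes are log2 differences ± SE from limma with adjusted p-values, and a call needed an adjusted p below 0.05 and a change of at least 2-fold. For the kits at 50 pg the SE and p can be too small, since arrays of unlike spread shared 1 spread.

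Replicate arrays of universal RNA stayed close down to 500 pg with BIIB and spread apart at the smallest inputs with every protocol that was run there. The mean Pearson r between replicates, across probe sets, was 0.982 ± 0.0039 (SD, 6 pairs) for one-cycle. With BIIB it was 0.959 ± 0.0092 at 5 ng, 0.943 ± 0.012 at 500 pg, 0.831 ± 0.013 at 50 pg and 0.669 ± 0.027 at 10 pg (6 pairs each, pairs sharing arrays). At 50 pg the single pairs gave 0.261 for two-cycle, 0.397 for Ovation and 0.392 for RiboAmp HS, against 0.985, 0.976 and 0.979 at 500 ng. The median SD between replicates at 50 pg was 0.64 (log2, mean of 6 pairs, 0.60 to 0.70) for BIIB and 1.43, 1.41 and 1.28 for the 3 kits (1 pair each). The mean profile correlated with one-cycle at r = 0.876 for BIIB at 5 ng and 0.859 at 50 pg. For two-cycle this r was 0.955 at 5 ng and 0.743 at 50 pg, for Ovation 0.826 and 0.460, and for RiboAmp HS 0.848 and 0.624 (means of 2 arrays). A mean over more arrays holds less noise, so these r of BIIB and the kits are not on equal terms. Single arrays at 50 pg gave 0.781 to 0.819 with BIIB and 0.247 and 0.843 with two-cycle. With Ovation they gave 0.320 and 0.444, and with RiboAmp HS 0.326 and 0.691. These correlations run across probe sets, which are not independent replicates.

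**Figure D1:**
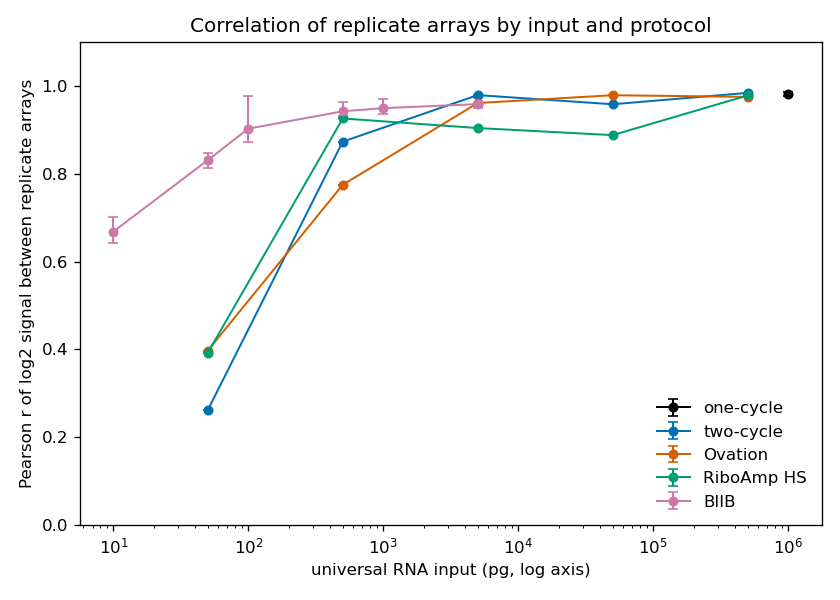
Pearson r between replicate arrays of universal RNA (vertical axis) against input in pg (log axis), with a point at the mean over pairs of arrays, a bar from the lowest to the highest pair where a group had more than 1 pair, and lines joining the inputs of each protocol. BIIB pairs lay between 0.814 and 0.847 at 50 pg, and the kit pairs at that input between 0.261 and 0.397.

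Beta-actin control probe sets showed how far each protocol favoured the 3' end of a transcript. The ratio of 3' to 5' signal was 1.19 ± 0.054 (SD, 4 arrays) for one-cycle, 2.54 ± 0.27 for two-cycle at 500 ng and 7.89 ± 1.89 at 50 pg (2 arrays each). It was 20.9 ± 2.28 for Ovation and 54.0 ± 3.46 for RiboAmp HS at 500 ng, and 5.41 ± 0.33 and 93.2 ± 48.3 at 5 ng (2 arrays each). The 2 Ovation arrays lay far apart at 500 pg, at 412 and 25.6, and at 50 pg, at 8.09 and 292. With BIIB it was 20.5 ± 3.82 at 5 ng, 16.01 ± 3.14 at 50 pg and 40.1 ± 34.6 at 10 pg (4 arrays each). The Gapdh control, a glycolytic enzyme transcript, gave 0.839 ± 0.024 for one-cycle, 10.2 ± 2.90 for BIIB at 5 ng and 24.7 ± 3.41 for RiboAmp HS at 500 ng. No test was run on these ratios.

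With BIIB, no transcript was called different at 1 ng or at 500 pg from 5 ng. At 1 ng limma called 0 of 11832 probe sets, with 1409 at an unadjusted p below 0.05. At 500 pg it called 0 of 11848, with 1773 at that unadjusted p. Of the genes of oxidative phosphorylation, which make the respiratory chain and ATP synthase, 0 of 77 were called at 1 ng (1 rose adjusted over the list alone) and 0 of 78 at 500 pg, with medians of 0.21 and 0.22. Their shift passed limma's camera test with its preset correlation, but adjusted p was 0.45 and 0.85 with an estimated correlation. The ribosomal proteins had 0 of 40 called at each input, with a median of 0.12 at 1 ng (adjusted p = 0.72 with an estimated correlation). At 500 pg arrays of the same replicate number deviated together, and limma also called 0 with the replicate number as a block. From 5 ng to 50 pg (5 inputs), replicates 1 and 2 stood apart from 3 and 4, with a 1st percentile of signal of at most 4.10 against at least 5.70 and a higher ratio of middle to 3' Gapdh signal at each input, and the labels name no batch. This split as a technical block, added after the data were seen, gave 0 calls at both inputs, as did each pair of replicates alone.

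At 100 pg the calls were mostly decreases of single transcripts. Sema3c, a guidance factor, was at -2.64 ± 0.27 (adjusted p = 0.012, 4 arrays against 4), Ttf1, which terminates ribosomal gene transcription, at -3.17 ± 0.39, and Rab22a, a small GTPase of endosomes, at -2.59 ± 0.27. Efcab7 (-2.67 ± 0.39) and Zfp445 (-2.50 ± 0.29) also fell. The increases were smaller: Tut1, a terminal uridylyltransferase, rose by 1.25 ± 0.18 (adjusted p = 0.032), Ptdss2, which makes phosphatidylserine, by 1.37 ± 0.24 and Pms2, a mismatch repair gene, by 1.35 ± 0.25. Of 77 oxidative phosphorylation genes 0 were called (2 rose adjusted over the list alone), and of 40 ribosomal proteins 0, with medians 0.39 and 0.40 above that of all probe sets, or 0.26 and 0.24 above it under quantile normalization (adjusted p = 0.33 and 0.37 with an estimated correlation). Among 11710 probe sets, 12 were higher and 80 lower, against 0 and 6 under quantile normalization. Replicates 1 and 2 at 100 pg correlated at 0.978 and the other pairs at 0.872 to 0.898, and with these 2 arrays averaged as 1, an alternative added after the data were seen, 5 calls were left. With replicates 1 and 2 against 3 and 4 as a technical block there were 192, with replicates 1 and 2 alone 1804 and with 3 and 4 alone 0. A fit of all 24 BIIB arrays of universal RNA gave 0. Without 1 array of 5 ng the calls numbered 0, 0, 0 and 2 (replicates 1 to 4), and without 1 of 100 pg 12, 0, 618 and 704.

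At 50 pg single transcripts were again lower. Crim1, which binds bone morphogenetic proteins, was at -4.15 ± 0.39 (adjusted p = 0.0047, 4 arrays against 4) and Dicer1, which cuts microRNA precursors, at -4.09 ± 0.45 (adjusted p = 0.0056). Usp48, a deubiquitinase (-3.54 ± 0.62), Wwp1, a ubiquitin ligase (-3.45 ± 0.40), and Slc6a6, the taurine transporter (-3.39 ± 0.37), fell too. Gramd3 (2.21 ± 0.37) and Vps11, a vacuolar sorting gene (1.56 ± 0.30), were the 2 that rose. Of 40 ribosomal proteins and 78 oxidative phosphorylation genes 0 were called, with medians 0.57 and 0.48 above that of all probe sets, or 0.22 and 0.23 above it under quantile normalization (adjusted p = 0.34 and 0.28 with an estimated correlation). In all, 2 of 11630 probe sets were higher and 117 lower, and quantile normalization, which moved the median change of all probe sets from -0.25 to -0.08, gave 2 and 26. Without 1 array of 5 ng the calls numbered 17, 14, 18 and 19 (replicates 1 to 4), and without 1 of 50 pg 238, 240, 400 and 425. The technical block gave 91, and either pair of replicates alone 0.

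At 10 pg some liver genes and single transcripts known from sperm were higher than at 5 ng, while many other transcripts were lower. Prm1, the protamine that packs sperm DNA, rose by 5.68 ± 0.48 (adjusted p = 0.0015, 4 arrays against 4), from a signal of 117 ± 72.4 (SD) to 12525 ± 5427. Ldhc, the lactate dehydrogenase of male germ cells, rose by 4.73 ± 0.51 and Smcp, a sperm mitochondrial protein, by 4.12 ± 0.53. Of 22 liver genes 8 passed the filter, and of these 5 rose and 0 fell (7 and 0 adjusted over the list alone; 6 rose under quantile normalization), among them Alb, the main plasma protein (4.96 ± 0.55), Ttr (3.57 ± 0.50), Fgb (2.48 ± 0.60) and Apoa1 (2.46 ± 0.54). A gene dim at 5 ng passes the filter only if bright at 10 pg. Without the filter 6 of 19 liver genes rose, the list median was 0.98, and adjusted p was 0.086 with an estimated correlation, against 0.022 with the filter. Ribosomal proteins had 4 of 39 higher (6 adjusted over the list alone), such as Rps28 (1.51 ± 0.42) and Rps29 (1.45 ± 0.40). Their median lay 1.72 above that of all probe sets (adjusted p = 0.039 with an estimated correlation, but p = 0.086 without the filter), and 0.35 above it with 0 calls under quantile normalization. Of 78 oxidative phosphorylation genes 1 rose, Ndufb10 (2.19 ± 0.44), and 3 fell, Ndufs1 (-2.18 ± 0.44) and the complex I assembly factors Ndufaf1 (-1.79 ± 0.50) and Ndufaf5 (-4.32 ± 0.51), with 1 and 2 adjusted over the list alone and a median 1.07 above that of all probe sets (adjusted p = 0.022 with an estimated correlation, but p = 0.086 without the filter), or 0.40 above it under quantile normalization.

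In the other lists few genes were called at 10 pg. Of 12 reference genes Actb rose by 1.47 ± 0.40 (not called under quantile normalization), while Gusb, a lysosomal enzyme (-2.86 ± 0.55), and Tfrc, the transferrin receptor (-2.57 ± 0.55), fell. Of 17 immediate early and heat shock genes 3 fell, Egr2 (-2.42 ± 0.45), Btg2 (-2.42 ± 0.47) and Atf3 (-2.28 ± 0.59), and 0 were called under quantile normalization. Of 37 proteasome subunits 1 fell, Psmb10 (-2.09 ± 0.42), and of 3 histone genes 1, H1f2 (-3.64 ± 0.87). The 14 mitotic genes had 0 calls and a median of -1.43. The largest decreases were Bnip2, a regulator of cell death (-5.40 ± 0.69), Nme7 (-5.35 ± 0.48) and Ddx46, a splicing helicase (-5.14 ± 0.46). Of 11650 probe sets 85 were higher and 1327 lower. Quantile normalization gave 130 and 346 and moved the median change of all probe sets from -0.78 to -0.25. Without 1 array of 5 ng the calls numbered 449, 431, 481 and 460 (replicates 1 to 4), and without replicate 1 or 2 of 10 pg 2119 and 2203. A fit of all 24 BIIB arrays of universal RNA gave 3319, the technical block 1276 and either pair of replicates alone 0.

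**Figure D2:**
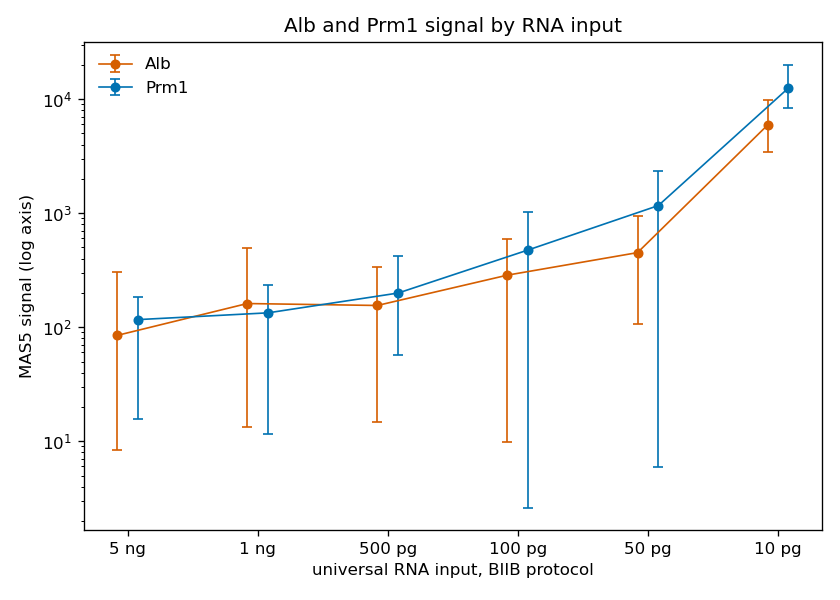
Signal of the Alb and Prm1 probe sets on a log axis against input of universal RNA labelled by BIIB, from 5 ng to 10 pg in equal steps, with points and lines at the means of 4 arrays and bars from the lowest to the highest array. Mean Alb signal was 84.7 at 5 ng and 5929 at 10 pg, and mean Prm1 signal 117 and 12525.

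With the two-cycle kit few transcripts passed the test between 50 pg and 500 ng. Cxcl14, a chemokine, rose by 4.89 ± 0.60 (adjusted p = 0.046, 2 arrays against 2) and Slco1a5, an organic anion transporter, by 4.00 ± 0.51. Bach1, a repressor of heme oxygenase (-4.42 ± 0.52), Rasa3, which inactivates Ras (-4.07 ± 0.47), and Rhox5, a homeobox gene (-3.94 ± 0.36), fell. No list member was called, though 2 of 12 reference genes, 3 of 14 mitotic genes and 1 of 18 immediate early and heat shock genes fell adjusted over the list alone, and 1 of 9 liver and 2 of 4 erythroid genes rose. Oxidative phosphorylation (79 genes, median -1.22) and proteasome subunits (37, median -1.31) shifted down by camera, with adjusted p = 0.58 and 0.57 with an estimated correlation. Of 16091 probe sets 7 were higher and 24 lower. Quantile normalization gave 11 and 127 and moved the median of all probe sets from -0.03 to -0.40. Without either 500 ng array 0 were called, while leaving out 50 pg replicate 1 or 2 gave 10885 and 2931 calls.

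With the Ovation kit, genes of the respiratory chain and the proteasome were lower at 50 pg than at 500 ng. Of 82 oxidative phosphorylation genes 46 fell and 1 rose (53 and 1 adjusted over the list alone; 42 and 1 under quantile normalization). Ndufs7 (-6.30 ± 0.81) and Ndufb8 (-5.94 ± 0.48) of complex I and Cox6b1 (-5.34 ± 0.52) and Cox5a (-5.29 ± 0.55) of cytochrome c oxidase were among them. The assembly factor Ndufaf3 fell too (-1.83 ± 0.51), and Cox8b, a subunit isoform of striated muscle, rose by 4.03 ± 0.58. Among 37 proteasome subunits, 13 fell and 0 rose (14 adjusted over the list alone), with Psmd4 at -4.32 ± 0.55. Both shifts held with an estimated correlation (adjusted p = 0.0071 and 0.04), at medians of -2.36 and -1.93 relative to all probe sets. The 2 arrays of 50 pg correlated at 0.397 with each other and at 0.320 and 0.444 with one-cycle. No list was compared here with probe sets of like signal level, so the shifts are not shown to be particular to these genes. Of 41 ribosomal proteins 9 fell, such as Rps3 (-5.14 ± 1.26), and 3 rose, such as Rpl39 (3.46 ± 0.61), but 16 fell and 1 rose under quantile normalization, which moved their median relative to all probe sets from -0.51 to -1.42. Of 22 liver genes 4 passed the filter, and 3 of these rose, Alb (3.21 ± 0.69), Apob (3.22 ± 0.65) and Cyp7a1, the first enzyme of bile acid synthesis (3.59 ± 0.87), with adjusted p = 0.25 for the list with an estimated correlation. Of 14 erythroid genes 2 passed it, and both rose, Klf1, a red cell transcription factor (3.47 ± 0.79), and Hba-a2, an alpha globin (2.89 ± 0.70). A gene dim at 500 ng passes only if bright at 50 pg; without the filter 4 of 19 liver and 2 of 8 erythroid genes rose (adjusted p = 0.071 and 0.30 with an estimated correlation).

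Outside the lists, Xist, the RNA of the inactive X chromosome, rose by 4.84 ± 0.67 and Stag1, a cohesin subunit, by 5.74 ± 1.73 in the Ovation arrays of 50 pg, while Elob, a subunit of elongin (-7.34 ± 1.02), and Cct7, a chaperonin subunit (-7.08 ± 0.66), fell. Of 12 reference genes 3 rose, among them Actb (4.17 ± 0.52), and 1 fell, Sdha (-4.25 ± 0.76), also a respiratory chain subunit. The median of the reference list turned from 0.34 to -0.23 under quantile normalization. Of 14 mitotic genes 3 fell (2 adjusted over the list alone), among them Aurka, a spindle kinase (-2.17 ± 0.57). In all, limma called 1489 probe sets higher and 2226 lower of 13839 (2 arrays against 2). The count was 0 without either 500 ng array and 7251 without 50 pg replicate 2.

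With the RiboAmp HS kit, erythroid and liver transcripts were among those higher at 50 pg than at 500 ng. Of 5 erythroid genes 3 rose (4 adjusted over the list alone), with Alas2, the red cell enzyme of heme synthesis, at 4.21 ± 0.59 and Klf1 at 2.83 ± 0.67. Of 12 liver genes 2 rose (6 adjusted over the list alone), Cyp7a1 (3.48 ± 0.87) and Hpx, which binds heme in plasma (2.79 ± 0.75). Without the filter, which favours genes bright at 50 pg, these counts were 3 of 8 and 2 of 19. Under quantile normalization 0 of either list were called, and adjusted p was 0.51 and 0.62 with an estimated correlation. Of 82 oxidative phosphorylation genes 3 rose and 6 fell (1 and 1 adjusted over the list alone), among them Cox8b at 4.11 ± 0.62 and Sdhd at -4.43 ± 0.72, and quantile normalization turned this to 2 and 1 (adjusted p = 0.73 with an estimated correlation). Of 13 mitotic genes 3 fell, Aurka (-2.32 ± 0.56), Aurkb (-2.85 ± 0.79) and Bub1 (-2.73 ± 0.65), with adjusted p = 0.51 for the list with an estimated correlation. Cldn3, a tight junction gene, rose by 5.53 ± 0.81, and Uba3, which activates NEDD8, was at -4.83 ± 0.83. Of 15326 probe sets 1581 were higher and 600 lower. Quantile normalization gave 225 and 574 and moved the median of all probe sets from 0.33 to -0.41. Without either 500 ng array 0 were called, and without 50 pg replicate 1 9127.

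The next comparisons set each protocol at 5 ng against one-cycle at 1 ug of the same RNA. BIIB and Ovation used cDNA and the others cRNA, and neither this nor input is separated here from protocol. With BIIB, ribosomal, respiratory chain, proteasome and immediate early genes were called in both directions. Thoc1, of the mRNA export complex THO (7.46 ± 0.15, 4 arrays against 4), Rpl27a, a ribosomal protein (6.86 ± 0.24), and Igk, the immunoglobulin kappa chain (6.70 ± 0.26), were higher. Ifitm2, an interferon-induced gene (-4.91 ± 0.20), and Pfn1, which binds actin (-4.18 ± 0.16), were lower. Of 17 immediate early and heat shock genes 8 fell, such as Btg2 (-3.38 ± 0.16), Nr4a1 (-2.81 ± 0.13) and Junb (-2.64 ± 0.13), and 2 rose (9 and 0 under quantile normalization), where 27.1% of all probe sets were lower. Their shift did not pass with the preset (adjusted p = 0.052) or an estimated correlation (adjusted p = 0.22). Of 78 oxidative phosphorylation genes 30 fell, such as Cox8a (-3.93 ± 0.21) and Atp5l (-3.87 ± 0.14), and 11 rose, such as Uqcrc2 (2.72 ± 0.13). Of 37 proteasome subunits 9 rose, such as Psmc1 (2.68 ± 0.12), and 2 fell, one being Psmb7 (-2.28 ± 0.11). Among 41 ribosomal proteins, 6 rose and 10 fell (3 and 11 under quantile normalization), and their median turned from 0.23 to -0.10 under quantile normalization. Hprt, a purine salvage gene of the reference list, rose by 2.27 ± 0.13, and 4 of 14 mitotic genes rose, Mki67 by 1.79 ± 0.15. All these list counts were the same adjusted over the list alone. Of 13119 probe sets 1804 were higher and 3553 lower. Quantile normalization gave 2339 and 2591 and moved the median of all probe sets from -0.28 to -0.02.

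With the two-cycle kit at 5 ng most list members stayed within the test. Cox8a, of cytochrome c oxidase (-4.13 ± 0.13, 2 arrays against 4), Eif4a1, a translation initiation helicase (-3.78 ± 0.13), and Otub1, a deubiquitinase (-3.72 ± 0.09), were the lowest, and Ajuba, a scaffold of cell junctions (2.25 ± 0.12), and Gsdme, a pore-forming gasdermin (1.86 ± 0.15), among the highest. Of 80 oxidative phosphorylation genes 12 fell, including Atp5l (-2.94 ± 0.14) and Uqcr10 (-2.84 ± 0.10), and 1 rose, Ndufa1 (1.11 ± 0.09), with the same counts adjusted over the list alone. Of 41 ribosomal proteins 4 fell (3 adjusted over the list alone), such as Rpl37a (-2.99 ± 0.13), and of 37 proteasome subunits 3 fell (3 adjusted over the list alone), such as Psma7 (-1.46 ± 0.10). Of 12 reference genes 0 were called with limma, and Btg2 was the 1 of 17 immediate early and heat shock genes that fell (-2.23 ± 0.09). Of 13226 probe sets 306 were higher and 1616 lower. Quantile normalization gave 477 and 1201 and moved the median of all probe sets from -0.06 to 0.07.

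With the Ovation kit at 5 ng, 38.6% of all probe sets were lower than with one-cycle, among them proteasome and respiratory chain genes. Among 37 proteasome subunits, 19 fell and 0 rose, such as Psmd7 (-2.57 ± 0.17) and Psmc5 (-2.46 ± 0.14). Of 79 oxidative phosphorylation genes 35 fell and 0 rose, such as Uqcrc1 (-2.97 ± 0.14) and Uqcr11 (-2.89 ± 0.13). Adjusted p was 0.21 and 0.24 with an estimated correlation, at medians of -0.40 and -0.20 relative to all probe sets, or -0.82 and -0.75 under quantile normalization. Among 41 ribosomal proteins, 14 fell and 1 rose, Rpl27a (6.37 ± 0.18), with adjusted p = 0.61 for the list with an estimated correlation and 5 fallen under quantile normalization. Of 14 mitotic genes 6 fell and 2 rose, with Aurka at -2.59 ± 0.11 and Cdc20 at -2.51 ± 0.12, and of 12 reference genes 4 fell and 2 rose. These list counts were the same adjusted over the list alone. Thoc1 (7.56 ± 0.20), Coq8a, of coenzyme Q synthesis (7.42 ± 0.18), and Igk (6.54 ± 0.31) were the highest, and Cyb5r3, a reductase (-5.61 ± 0.13), and Csrp1, a LIM protein (-5.52 ± 0.14), the lowest. Of 13315 probe sets 2287 were higher and 5135 lower (2 arrays against 4). Quantile normalization gave 2876 and 3424 and moved the median of all probe sets from -0.64 to -0.20.

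With the RiboAmp HS kit at 5 ng, 28.4% of all probe sets were lower and 11.9% higher than with one-cycle, and members of most lists were called in both directions. Of 17 immediate early and heat shock genes 10 fell and 2 rose, with Btg2 at -4.40 ± 0.18, Junb at -3.68 ± 0.19 and Jun at -3.19 ± 0.16 (adjusted p = 0.52 with an estimated correlation). Of 80 oxidative phosphorylation genes 31 rose, such as Ndufa13 (3.04 ± 0.28) and Ndufb7 (2.89 ± 0.18), and 18 fell, such as Atp5l (-5.64 ± 0.37), with adjusted p = 0.49 with an estimated correlation. Of 41 ribosomal proteins 15 rose, such as Rpl14 (3.06 ± 0.18), and 6 fell, but 4 rose and 9 fell under quantile normalization (adjusted p = 0.52 with an estimated correlation). Of 37 proteasome subunits 6 rose and 9 fell, Psmb7 by the most (-4.97 ± 0.49), and of 14 mitotic genes 7 fell and 1 rose. These list counts were the same adjusted over the list alone. Malat1, a nuclear long noncoding RNA (-6.81 ± 0.33), and Eif4a1 (-5.52 ± 0.15) were among the lowest, and Sf3b4, a splicing factor (6.18 ± 0.45), and Ezr, which links actin to the membrane (4.75 ± 0.25), among the highest. Of 13551 probe sets 1614 were higher and 3850 lower (2 arrays against 4). Quantile normalization gave 2319 and 2917 and moved the median of all probe sets from -0.29 to 0.01.

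At 50 pg against one-cycle, 28.6% of all probe sets were lower and 8.24% higher with BIIB. Among 37 proteasome subunits, 5 rose, such as Psmc1 (2.92 ± 0.37) and Psmd13 (2.03 ± 0.25), and 3 fell, such as Psmb7 (-2.12 ± 0.40), and the list shifted up by 0.99 relative to all probe sets (adjusted p = 0.048 with an estimated correlation), a shift of 0.26 under quantile normalization. Of 17 immediate early and heat shock genes 9 fell and 0 rose, such as Btg2 (-3.86 ± 0.38), with adjusted p = 0.19 with an estimated correlation. Among 41 ribosomal proteins, 12 rose and 7 fell, but 5 rose and 9 fell under quantile normalization (adjusted p = 0.37 with an estimated correlation). Of 79 oxidative phosphorylation genes 15 rose and 24 fell, with Uqcrc2 at 2.67 ± 0.25 and Cox8a at -3.75 ± 0.28. Of 14 mitotic genes 3 rose and 2 fell (adjusted p = 0.19 with an estimated correlation). These list counts were the same adjusted over the list alone. Thoc1 (7.98 ± 0.25), Rpl27a (7.31 ± 0.33) and Igk (6.85 ± 0.29) were the highest, and Ccni, a cyclin (-4.93 ± 0.35), and Rpl37 (-4.75 ± 0.31) among the lowest. Of 12883 probe sets 1061 were higher and 3682 lower (4 arrays against 4). Quantile normalization gave 1445 and 2177 and moved the median of all probe sets from -0.66 to -0.17.

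With two-cycle at 50 pg, few list members passed the test against one-cycle. Of 9 liver genes 2 rose, Hpx (3.46 ± 0.40) and Apoa1 (2.93 ± 0.60), or 6 adjusted over the list alone, and of 4 erythroid genes 1 rose, Klf1 (2.55 ± 0.48), or 3. Without the filter 2 of 19 and 3 of 8 rose. Of 81 oxidative phosphorylation genes 8 fell (10 fell and 1 rose adjusted over the list alone), such as Atp5l (-4.69 ± 0.59) and Cox8a (-3.83 ± 0.44). Of 37 proteasome subunits 3 fell (4 adjusted over the list alone), such as Psmb7 (-3.73 ± 0.81). For these 4 lists adjusted p was 0.52 with an estimated correlation. Ywhaz, of the reference list, fell by 2.20 (log2, ± 0.38) and Plk1, a mitotic kinase, by 2.03 (± 0.27). Cxcl14 (4.86 ± 0.54, adjusted p = 0.02, 2 arrays against 4) and Krt14, a keratin (4.07 ± 0.69), were among the highest, and Lpar1, a lipid receptor (-4.19 ± 0.27), among the lowest. Of 17230 probe sets 598 were higher and 919 lower, and quantile normalization moved the median of all probe sets from -0.05 to -0.29. Without any 1 one-cycle array the count of 1517 was 0. Leaving out 50 pg replicate 1 or 2 gave 12638 and 4859.

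With Ovation at 50 pg, most respiratory chain and proteasome genes were lower than with one-cycle. Of 83 oxidative phosphorylation genes 59 fell and 2 rose (62 and 2 adjusted over the list alone), with Cox5a at -6.52 ± 0.40 and Ndufb8 at -5.90 ± 0.25. The 2 that rose were Cox8b (4.05 ± 0.28) and Cox6b2, the isoforms of striated muscle and of testis (2.78 ± 0.35). Among 37 proteasome subunits, 25 fell and 0 rose (26 adjusted over the list alone), with Psmd4 at -5.45 ± 0.26. Both lists had a median of -2.52 relative to all probe sets (adjusted p = 0.024 each with an estimated correlation). Neither was compared with probe sets of like signal level. Of 41 ribosomal proteins 20 fell and 4 rose (23 and 5 adjusted over the list alone; 28 and 2 under quantile normalization), and of 14 mitotic genes 8 fell and 1 rose, with Aurka at -3.91 ± 0.36 (adjusted p = 0.25 with an estimated correlation). Of 5 liver genes 4 rose, such as Alb (3.98 ± 0.76), and of 3 erythroid genes 2, such as Hba-a2 (5.12 ± 0.40), or 7 of 19 and 5 of 8 without the filter, with adjusted p = 0.30 for both lists with an estimated correlation. Coq8a (9.62 ± 0.45) and Map3k12, a neuronal kinase (9.48 ± 0.34), were the highest, and Pabpn1, which binds poly(A) tails (-7.05 ± 0.31), and Ctsz, a cathepsin (-6.82 ± 0.50), the lowest. Of 16725 probe sets 2841 were higher and 4968 lower (2 arrays against 4), and quantile normalization moved the median of all probe sets from -0.46 to -0.25. The count of 7809 was 12126 without 50 pg replicate 2.

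With RiboAmp HS at 50 pg, erythroid and liver genes were among the 16.5% of probe sets called higher than with one-cycle, and mitotic and immediate early genes among the 17.5% called lower. Of 5 erythroid genes 4 rose, such as Alas2 (3.99 ± 0.41) and Hbb-b2, a beta globin (3.64 ± 0.40), and of 10 liver genes 4, such as Cyp2c29 (3.01 ± 0.43), or 7 of 8 and 8 of 19 without the filter. Adjusted p was 0.46 and 0.64 with an estimated correlation. Of 14 mitotic genes 6 fell and 0 rose, with Aurka at -4.08 ± 0.30, and of 18 immediate early and heat shock genes 9 fell and 0 rose (10 and 1 adjusted over the list alone), with Jun at -3.77 ± 0.84. Adjusted p was 0.46 for both with an estimated correlation. Of 83 oxidative phosphorylation genes 26 fell and 9 rose (28 and 10 adjusted over the list alone; 21 and 14 under quantile normalization), such as Atp5l (-6.41 ± 0.34) and Sdhd (-5.15 ± 0.25), and of 38 proteasome subunits 9 fell and 2 rose, with adjusted p = 0.64 and 0.46 with an estimated correlation. Malat1 (-7.50 ± 0.48), Eif4a1 (-7.28 ± 0.38) and Pfn1 (-7.21 ± 0.37) were the lowest, and Cldn3 (5.25 ± 0.68) among the highest. Of 17292 probe sets 2848 were higher and 3032 lower (2 arrays against 4), and quantile normalization moved the median of all probe sets from 0.00 to -0.26. The count of 5880 was 12398 without 50 pg replicate 1, and 3599, 3233, 3142 and 3144 without each of the one-cycle arrays.

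At 50 pg the kits were also set against BIIB, with cRNA against cDNA except for Ovation. For two-cycle the 9 calls were all lower, among them Atp5a1, the ATP synthase alpha subunit (-7.00 ± 0.94, adjusted p = 0.0064, 2 arrays against 4), Igk (-6.88 ± 0.98), Rpl27a (-6.50 ± 1.01) and Thoc1 (-6.28 ± 0.94). Of 41 ribosomal proteins and of 80 oxidative phosphorylation genes 1 each fell (2 fell and 1 rose, and 1 fell, adjusted over the list alone), with adjusted p = 0.50 for both with an estimated correlation. Of 10 liver and 4 erythroid genes 0 were called, or 3 each higher adjusted over the list alone. Limma called 0 higher and 9 lower of 16318 probe sets, and quantile normalization moved the median of all probe sets from 0.77 to -0.20. The count was 6592 without two-cycle replicate 1 and 0 without replicate 2.

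For Ovation, proteasome and respiratory chain genes were lower than with BIIB at 50 pg. Of 37 proteasome subunits 21 fell and 0 rose (22 adjusted over the list alone), with Psmb3 at -7.05 ± 0.86, and of 82 oxidative phosphorylation genes 38 fell and 2 rose (43 and 3 adjusted over the list alone), with Ndufb8 at -5.83 ± 0.73. Their medians were -3.42 and -2.69 relative to all probe sets (adjusted p = 0.012 and 0.03 with an estimated correlation). Neither list was compared with probe sets of like signal level. Among 41 ribosomal proteins, 16 fell and 3 rose (20 and 3 adjusted over the list alone), with Rplp0 at -6.05 ± 0.90 (adjusted p = 0.27 with an estimated correlation). Of 14 mitotic genes 7 fell and 0 rose (7 adjusted over the list alone; 3 under quantile normalization), with Tpx2, a spindle assembly factor, at -5.21 ± 0.92 (adjusted p = 0.096 with an estimated correlation). Of 8 liver genes 3 rose, such as Apob (3.43 ± 0.79), with adjusted p = 0.27 with an estimated correlation, and of 6 histone genes 2 rose, such as H1f2 (5.43 ± 0.74). Ewsr1 (7.84 ± 0.89) and Map3k12 (7.35 ± 0.73) were among the highest, and Cct7 (-8.05 ± 0.88), Prpf6, a splicing factor (-7.79 ± 0.77), and Ybx1, which binds mRNA (-7.57 ± 1.13), the lowest. Of 15381 probe sets 2086 were higher and 1655 lower (2 arrays against 4). Quantile normalization gave 1406 and 1953 and moved the median of all probe sets from 0.37 to -0.11. The count of 3741 was 1682, 2059 and 2026 without BIIB replicate 1, 2 or 3.

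For RiboAmp HS, some liver and erythroid genes were called higher than with BIIB at 50 pg, but neither list held with an estimated correlation. Of 12 liver genes 5 rose and 0 fell (6 adjusted over the list alone), such as Cps1, of the urea cycle (3.97 ± 0.87), and Tdo2, which degrades tryptophan (3.61 ± 0.85). Of 6 erythroid genes 4 rose, such as Alas2 (3.51 ± 0.82) and Klf1 (3.22 ± 0.81). Without the filter 6 of 19 and 4 of 8 rose. Under quantile normalization 0 of either list were called, and adjusted p was 0.52 for both with an estimated correlation. Of 38 proteasome subunits 3 fell and 1 rose (2 and 1 adjusted over the list alone), with Psmc1 at -5.37 ± 0.98, and of 82 oxidative phosphorylation genes 6 fell and 2 rose (5 and 1), with Uqcrb at 5.18 ± 0.87. Adjusted p was 0.18 and 0.52 with an estimated correlation. Sf3b4 (7.27 ± 0.79, adjusted p = 0.015) was the highest and Thoc1 (-6.43 ± 0.91) among the lowest. Of 16082 probe sets 1520 were higher and 385 lower (2 arrays against 4). Quantile normalization gave 109 and 177 and moved the median of all probe sets from 0.69 to -0.17. The count of 1905 was 5637 and 0 without RiboAmp HS replicate 1 or 2, and 2, 1, 1 and 1 without each of the 4 BIIB arrays.

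In the tissue panel, each tissue was set against the mean of the other 7 with both protocols in 1 fit, so each group held 2 arrays. In the arrays labelled brain, liver genes were high. All 19 measured members of the liver list rose, with a median of 8.13, such as Fgb, a fibrinogen chain (9.17 ± 0.38), Alb (7.76 ± 0.52) and Cyp7a1 (5.25 ± 0.38). Of 16 brain genes 1 rose there, Slc1a2, the glial glutamate transporter (2.64 ± 0.35), and 9 fell, such as Mbp, a myelin protein (-2.44 ± 0.38). In the arrays labelled liver, all 16 brain genes rose, with a median of 5.28, such as Snap25, a synaptic protein (8.61 ± 0.46), Mbp (8.38 ± 0.38) and Mobp (8.20 ± 0.49). Of 19 liver genes 16 fell there (17 adjusted over the list alone), such as Alb (-5.05 ± 0.52) and Hp, haptoglobin (-6.54 ± 0.28), and 1 rose, Ttr (4.53 ± 0.33). The shift of the liver list held with an estimated correlation under both labels (adjusted p = 7.1e-05 and 0.0038), and that of the brain list in the arrays labelled liver (adjusted p = 0.00054), but not in those labelled brain (0.22). Alb signal was 389047 by one-cycle and 1383220 by BIIB in the arrays labelled brain, and 65.2 and 379 in those labelled liver. Quantile normalization moved the median of all probe sets under the brain label from -0.42 to -0.18 and the calls from 1628 higher and 3639 lower (30.9% higher) to 1934 and 2479 (43.8% higher). Under the liver label 2318 were higher and 2944 lower, all of 15180 probe sets.

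The embryo arrays held fetal genes, and genes of the liver and erythroid lists with them. Of 17 embryo genes 15 rose and 0 fell (16 adjusted over the list alone), such as Afp, the fetal albumin (9.49 ± 0.37), Hbb-y, an embryonic globin (7.81 ± 0.41), Col2a1, of cartilage (7.78 ± 0.39), and Igf2, a fetal growth factor (6.54 ± 0.37). Liver genes rose too, 14 of 19 with 1 lower, at a median of 4.42, and 4 of 7 erythroid genes, such as Klf1 (3.62 ± 0.28). These 3 shifts held with an estimated correlation (adjusted p = 0.0022, 0.0012 and 0.027). In spleen all 16 spleen genes rose, such as Ighm, the IgM heavy chain (6.80 ± 0.46), Cd79b, of the B cell receptor (5.20 ± 0.28), and Cd3e, of the T cell receptor complex (2.05 ± 0.49). There 5 of 7 erythroid genes rose, such as Slc4a1, the red cell anion exchanger (6.28 ± 0.35), and outside the lists Car1, the red cell carbonic anhydrase (7.54 ± 0.40), and Mpo, of neutrophil granules (6.99 ± 0.39). Adjusted p was 0.0014 and 0.0085 with an estimated correlation. The calls numbered 1566 higher and 867 lower in embryo (64.4% higher; 1426 and 1189, 54.5%, under quantile normalization) and 2240 and 2959 in spleen. Without the BIIB embryo array the embryo count was 1076.

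Heart, kidney, lung and ovary arrays each held the genes of their label. In heart all 20 heart genes rose, such as the myosin light chains Myl2 (9.58 ± 0.46) and Myl3 (9.45 ± 0.46), Mb, myoglobin (9.30 ± 0.32), and Nppa, the atrial natriuretic peptide (8.56 ± 0.38). In kidney 18 of 19 rose, such as Kap, an androgen-regulated protein of the proximal tubule (10.10 ± 0.31), Umod, of the thick ascending limb (8.48 ± 0.33), and Slc34a1, a phosphate transporter (7.84 ± 0.45), while Slc12a2 was at 0.21 ± 0.24. In lung all 17 rose, such as Scgb1a1, of club cells (9.69 ± 0.33), and the surfactant proteins Sftpa1 (9.52 ± 0.43) and Sftpc (8.92 ± 0.44). In ovary 9 of 20 list genes passed the filter and all 9 rose, such as Hsd3b1 (8.87 ± 0.25) and Cyp11a1 (8.51 ± 0.46) of steroid synthesis, Inha, an inhibin subunit (7.57 ± 0.51), and the oocyte genes Zp2 (4.03 ± 0.29) and Gdf9 (3.67 ± 0.29). Without the filter, which leaves out genes dim in most tissues, 20 of 20, 18 of 19, 17 of 17 and 12 of 16 rose, at an ovary median of 3.90. Counts adjusted over the list alone were the same as the first, and all 4 shifts held with an estimated correlation (adjusted p = 4.5e-05, 0.00016, 0.00012 and 0.00036), also without the filter. In ovary 4 of 7 erythroid genes fell (adjusted p = 0.013 with an estimated correlation). Calls higher and lower were 1575 and 1852 in heart, 1614 and 1883 in kidney, 1881 and 1366 in lung, and 1340 and 1000 in ovary. Without the BIIB array of the tissue these counts were 1924 in heart, 2025 in kidney, 1536 in lung and 795 in ovary, and without the one-cycle array 2222, 2049 and 1150 in kidney, lung and ovary.

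**Figure D3:**
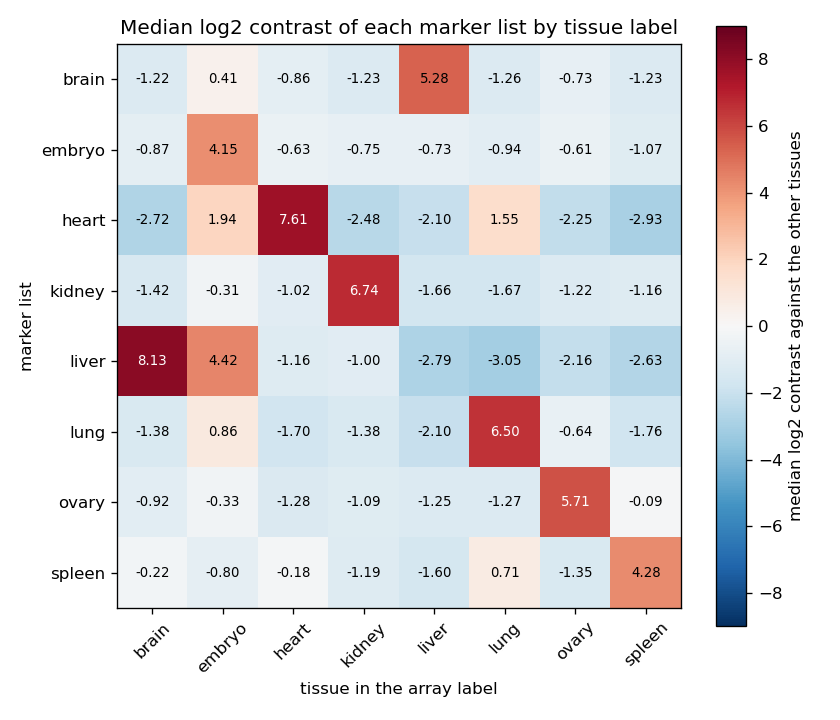
Median log2 change of the members of each tissue's gene list that passed the filter (vertical axis) in the arrays of each tissue label (horizontal axis), against the mean of the other 7 tissues, with both protocols in 1 fit and the value written in each cell. Each list was highest in its own label except brain, at 5.28 in the arrays labelled liver, and liver, at 8.13 in the arrays labelled brain.

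The 2 protocols were then compared on the same tissue ratios, the question being whether BIIB from 500 pg keeps the differences that one-cycle finds from 1 ug. Across 15180 probe sets, the log2 ratio of a tissue to the mean of all 8 tissues correlated between protocols at r = 0.854 in the arrays labelled brain, 0.756 in embryo, 0.739 in heart, 0.8294 in kidney, 0.868 in the arrays labelled liver, 0.785 in lung, 0.764 in ovary and 0.845 in spleen. The median was 0.807, and the highest r with another label was 0.150. Of the probe sets over 2-fold from that mean with one-cycle, 91.3% to 96.4% had the same sign with BIIB. The slope of BIIB on one-cycle was 0.818 to 0.892. These r are across probe sets, which are not independent replicates, with 1 array per tissue and protocol.

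Among sorted lymphocytes, 100 B cells differed from 100 T cells in the genes that define these cells. The class II genes H2-Ea (10.85 ± 0.99, adjusted p = 0.00018, 2 arrays against 2 in a fit of 12), H2-Aa (8.96 ± 1.01) and H2-Eb1 (8.03 ± 0.99), which present antigen, were higher in B cells. So were Cd79b, of the B cell receptor (8.93 ± 1.07), Igk (7.70 ± 1.01), Ms4a1, which encodes CD20 (6.93 ± 1.15), and Cr2, a complement receptor (6.17 ± 1.04). Cd3g, of the T cell receptor complex (-7.98 ± 1.02, adjusted p = 0.0018), Trav9d-3, a T cell receptor segment (-7.19 ± 1.01), Ms4a4b (-6.91 ± 0.96), Cd5 (-6.17 ± 1.05) and Cd28, a costimulatory receptor (-5.94 ± 1.00), were lower. Scd1, a fatty acid desaturase of the B cell list (7.96 ± 0.98), was also higher in B cells. So were Lmo2 (8.51 ± 1.06) and Plek (8.02 ± 1.42), which are on neither list. Of 26 B cell genes 11 rose and 0 fell (22 adjusted over the list alone), and of 22 T cell genes 6 fell and 0 rose (15 adjusted over the list alone). Both shifts held with an estimated correlation (adjusted p = 0.00056 and 0.0003). Genes that did not pass included Cd79a (3.77 ± 1.09, adjusted p = 0.34), Cd3e (-2.60 ± 1.35), Cd8a (-3.87 ± 1.00), Cd4 (-0.33 ± 1.32) and Pax5, the B cell transcription factor (-0.28 ± 1.17).

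Limma called 0 of 8 NK cell, 13 myeloid, 4 erythroid and 7 plasma cell genes. Adjusted over the list alone, 1 myeloid gene was higher in B cells. Limma also called 0 of 8 mitotic, 14 immediate early and heat shock, 41 ribosomal, 82 oxidative phosphorylation, 38 proteasome and 12 reference genes. Adjusted over the list alone this stayed 0. Cells in both samples cannot show, and 0% of simulated log2 changes of 3 were recovered, so 0 calls show neither purity nor equality. Over all 18318 probe sets 30 were higher and 14 lower, with 1199 at an unadjusted p below 0.05. Without 1 unmixed array the count was 8 and 15 (T cell replicates 1 and 2) and 15 and 22 (B cell replicates 1 and 2). A slope on B cell share gave 85 calls over the 12 arrays and 217 over all 18.

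Mixtures of T and B cells tested whether the share of B cells could be read from the profile. The share was estimated from 20 T cell and 25 B cell genes, with the unmixed 500-cell arrays as the ends. At nominal shares of 0, 20, 40, 60, 80 and 100% the 2 arrays of 100 cells gave -3.02 and -1.08, 26.6 and 26.9, 43.8 and 56.3, 63.0 and 71.2, 78.7 and 94.6, and 105 and 100.8%. Over the 12 arrays Pearson's r with the nominal share was 0.986 and Spearman's rho 0.989 (permutation p = 1e-05 each, two-sided, the smallest that 100000 permutations can give). Without the 2 arrays at a nominal 0%, with those at 100% kept, r was 0.982, and over the 8 mixed arrays alone 0.969. The estimates lay 5.25 percentage points above nominal on average, with a root mean square difference of 7.94. The B cell genes alone gave r = 0.952 and a mean difference of 12.2 points, and the T cell genes alone 0.977. The 500-cell mixtures gave 20.1, 39.3, 63.5 and 78.2% at 20, 40, 60 and 80%. All cells were from 1 mouse, so the spread between mice was not measured.

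**Figure D4:**
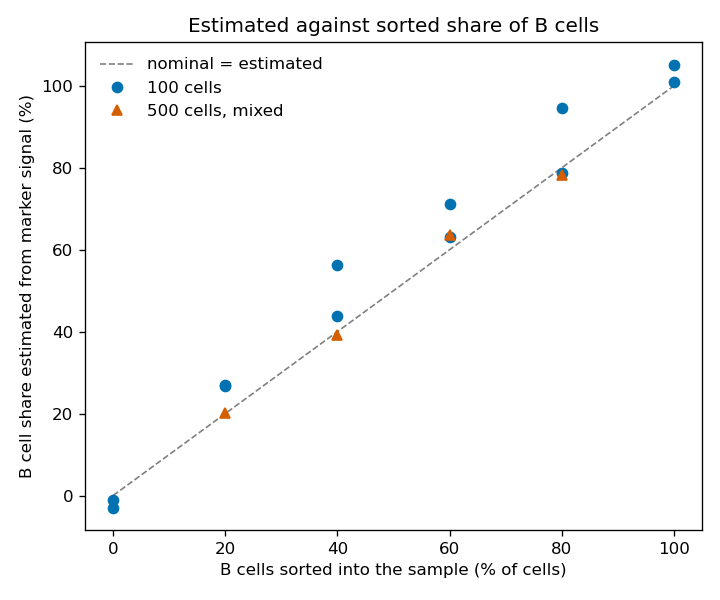
Estimated against nominal percent of B cells, with 1 point per array of 100 cells and per mixed array of 500 cells and a dashed line where both are equal. The 12 arrays of 100 cells followed the nominal share at r = 0.986, with the widest pair at 80%, 78.7 and 94.6%.

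The B to T difference at 100 cells was set against that at 500 cells, where each unmixed group had 1 array. All 44 probe sets called at 100 cells had the same sign at 500 cells, and 43 of them differed there by over 2-fold. Across 17263 probe sets, which are not independent replicates, the differences correlated at r = 0.207. Replicate arrays of 100 cells correlated at 0.590 to 0.651. A test of whether the slope on the share of B cells differed between 100 and 500 cells gave 0 calls with limma, with 545 probe sets at an unadjusted p below 0.05.

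In sorted RAW267 cells, single transcripts such as Prm1, the sperm protamine, and Ttr, a liver gene, were lower with more cells, and Aspm was among those higher. Over 50 to 10000 cells the fitted change was -5.23 ± 0.88 for Prm1 (adjusted p = 0.025, 11 arrays), -4.38 ± 0.73 for Fabp9, a fatty acid binding protein of testis, -5.22 ± 1.23 for Ttr and -4.39 ± 0.98 and -4.89 ± 1.06 for the synaptic genes Snap25 and Cplx1. Aspm, of the mitotic spindle (4.12 ± 0.55, adjusted p = 0.016), Smc1a, a cohesin subunit (4.23 ± 0.97), and Diaph2, an actin regulator (4.43 ± 0.96), rose. Of 20 macrophage genes 1 rose, Cybb, of the phagocyte oxidase (1.89 ± 0.40), and 2 rose and 2 fell adjusted over the list alone (adjusted p = 0.28 for the list with an estimated correlation). Of 5 liver genes 1 fell, Ttr (2 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). Of 77 oxidative phosphorylation genes 0 were called, at a median of -0.55 relative to all probe sets, or -0.28 under quantile normalization (adjusted p = 0.02 with an estimated correlation, but p = 0.19 without the filter). Of 14 mitotic genes 0 were called, also adjusted over the list alone, at 9 positive and 5 negative values (adjusted p = 0.84 with an estimated correlation). The 2 T cell, 9 B cell and 1 erythroid genes measured had 0 calls with limma, also adjusted over the list alone. Of 11479 probe sets 260 rose and 78 fell, with 2969 at an unadjusted p below 0.05. Quantile normalization gave 208 and 111 and moved the median of all probe sets from 0.29 to 0.13.

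The RAW267 trend depended on single arrays and on the smallest samples. The count of 338 was 4 and 5 without 1 array of 10000 cells, 2 and 3 without 1 of 5000, 75 and 52 without 1 of 1000, 45 and 104 without 1 of 50, and 1373 without the array of 100 cells. Without both arrays of 50 cells, an alternative added after the data were seen, limma called 0. As 10000 against 50 cells in a fit of group means the count was 1352. Replicates correlated at 0.960 for 10000 cells, 0.966 for 5000, 0.952 for 1000, 0.930 for 500 and 0.758 for 50.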

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

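Both tests of why replicates 1 and 2 resembled each other at 100 pg were chosen only after the result was seen. Of 49 groups and measures checked for an array or a pair that stood apart from the others, 4 met Dixon's criterion, and chance alone meets it in about 1 in 20. The beta-actin ratio of 3' to 5' signal was 1.27 in one-cycle replicate 1 of universal RNA, against 1.16 to 1.17 in the other 3 arrays. With BIIB at 10 pg it was 91.9 in replicate 2, against 19.7 to 25.1 in the others. The r between BIIB replicates 1 and 2 was 0.972 at 1 ng, where the other pairs had 0.937 to 0.949, and 0.978 at 100 pg, where they had 0.872 to 0.898. Pairs that share an array are not independent, so the chance rate is only approximate for r.

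The r of 0.978 at 100 pg was above every pair at 5 ng, 1 ng and 500 pg, of which the highest had 0.973. A batch shared by replicates 1 and 2 at each input stays open: from 5 ng to 50 pg these arrays stood apart from 3 and 4 in the 1st percentile of signal (at most 4.10 against at least 5.70), but their r exceeded that of pairs across by 0.0861 at 100 pg, by 0.0149, 0.0241 and 0.0251 at 5 ng, 1 ng and 500 pg, where r across was 0.940 to 0.958 and left less room, and by 0.0177 at 50 pg and -0.0249 at 10 pg, where more noise could hide a batch. A candidate explanation is that 1 amplified product was hybridised to 2 arrays, but the r of 0.978 that this needs is the value that raised the question. No columns held identical values, with 0 found. The universal RNA was the same on all arrays, and no biological explanation was tested.

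The change from 5 ng to 50 pg differed between each kit and BIIB by a test of the difference itself, an interaction term in limma over 12 arrays. The interaction term called 5 of 14662 probe sets for two-cycle (3 more positive in the kit, 2 more negative), 1863 of 13667 for Ovation (843 and 1020) and 177 of 14716 for RiboAmp HS (165 and 12).

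The hybridisation controls, bacterial transcripts that entered no comparison, were far brighter at 50 pg with the kits than in the 4 one-cycle arrays, where their median signal was 4669 to 5636. It was 298781 and 944518 in the 2 arrays of two-cycle, 1234320 and 563594 in those of Ovation, and 308847 and 1528030 in those of RiboAmp HS. With BIIB it was 62264 ± 21749 (SD, 4 arrays) at 5 ng, 62299 ± 27893 at 50 pg and 223685 ± 52965 at 10 pg. The 12 BIIB arrays of 100 sorted lymphocytes, at 155240 to 812156, overlapped the range of the kits at 50 pg.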

How the results depend on the processing

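Settings marked here as added were chosen after the data were seen, and all others before. Among the named genes recomputed, 0 changed direction, but under quantile normalization the median of 22 of 263 gene lists by comparison changed sign and 7 had more calls the other way. Among named genes called in their comparisons, leaving out 1 array kept the call in 3481 cases and ended the call in 416, and other settings in 2504 and 215. Fewer arrays or another filter change the number of tests and arrays, and for all other changes the cause was not tested. The counts below are calls, with the count of the main setting in the report. Signal near the pseudocount of 125 limits what dim probe sets can show.

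Quantile normalization gave 6 at 100 pg, 28 at 50 pg and 476 at 10 pg against 5 ng, 138 (two-cycle) and 799 (RiboAmp HS) for 50 pg against 500 ng, and 286 for RiboAmp HS against BIIB. A pseudocount of 2.5% gave 56 at 100 pg, and one of 10% gave 168 at 100 pg, 12 for two-cycle at 50 pg against 500 ng and 21 for two-cycle against BIIB. Without the filter the counts were 264 at 50 pg, 0 for two-cycle at 50 pg against 500 ng and 108 for the RAW267 trend. With the filter at 40% they were 2 at 500 pg, 49 at 50 pg, 781 at 10 pg, 268, 2374 and 1129 for 50 pg against 500 ng (two-cycle, Ovation, RiboAmp HS) and 1002 for RiboAmp HS against BIIB. All BIIB universal arrays in 1 fit gave 0 at 100 pg and 3319 at 10 pg.

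With a replicate block the counts were 0 at 100 pg, 0 at 50 pg and 498 at 10 pg against 5 ng, 0 (two-cycle) and 1449 (RiboAmp HS) for 50 pg against 500 ng, 0, 1729 and 159 for 50 pg against one-cycle (two-cycle, Ovation, RiboAmp HS), 758 (Ovation) and 14 (RiboAmp HS) against BIIB, and 1153 for the RAW267 trend, where the array of 100 cells has no number and so drops out of the block fit. These comparisons did not meet the rule for pairing (at least 3 pairs, each correlated above 0.1; for RAW267, 1 of 10 pairs of cell numbers), though BIIB replicates 1 and 2 differed from 3 and 4 at 5 inputs, and the block moved no other count by over 1.5 times. At 500 pg, where the numbers paired the arrays, it changed no call.

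Added settings at 100 pg gave 192 with a technical block of replicates 1 and 2 against 3 and 4, 1804 with replicates 1 and 2 alone, 0 with 3 and 4 alone and 5 with replicates 1 and 2 of 100 pg averaged. At 50 pg and at 10 pg either pair of replicates alone gave 0. Without liver and testis transcripts the 10 pg count was 1231. The RAW267 trend without 50 cells gave 0, and as 10000 against 50 cells in group means (a planned setting) 1352. B against T cells as a slope gave 85 over the 12 arrays of 100 cells and 217 over all 18.

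The median r of tissue ratios between protocols (0.807) was 0.728 without the filter and 0.709 as Spearman's rho. The r between the 100-cell and 500-cell differences (0.207) was 0.193 and 0.227 with pseudocounts of 2.5 and 10%, 0.176 without the filter and 0.273 with it at 40%. The median SD at 50 pg was, for BIIB (0.637), 0.585 with 10%, 0.520 without the filter and 0.594 with it at 40%. For two-cycle (1.43) it was 1.496 and 1.31 with 2.5 and 10%, 1.30 with quantile normalization, 1.25 without the filter and 1.56 at 40%. For Ovation (1.41) these were 1.51 and 1.24, then 1.04 without the filter and 1.496 at 40%, and for RiboAmp HS (1.28) 1.35 and 1.17, then 1.06 and 1.35. Of 129 list shifts 58 held with an estimated correlation. Of these 58, 54 held without the filter (an added setting), and 4 did not: liver, ribosomal and oxidative phosphorylation genes at 10 pg (adjusted p = 0.086 each) and oxidative phosphorylation in RAW267 (0.19).

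Leaving out 1 array gave 0 to 0 at 1 ng and at 500 pg, 0 to 704 at 100 pg, 14 to 425 at 50 pg and 431 to 2203 at 10 pg. For 50 pg against 500 ng it gave 0 to 10885 (two-cycle), 0 to 7251 (Ovation) and 0 to 9127 (RiboAmp HS). Against one-cycle it gave 5252 to 5485 (BIIB), 1838 to 2052, 7305 to 7658 and 5183 to 6126 at 5 ng, and 3519 to 5217, 0 to 12638, 6036 to 12126 and 3142 to 12398 at 50 pg, in the order BIIB, two-cycle, Ovation, RiboAmp HS. Against BIIB the kits gave 0 to 6592, 1682 to 5498 and 0 to 5637. By label, the range was 3921 to 5304 for brain, 1076 to 2491 for embryo, 1924 to 3450 for heart, 2025 to 3553 for kidney, 3608 to 5349 for liver, 1536 to 3334 for lung, 795 to 2393 for ovary and 3467 to 5260 for spleen. It was 8 to 22 for B against T cells and 2 to 1373 for the RAW267 trend.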

Other observations

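The test of mixed RNA and both tests of dim probe sets were chosen only after the result was seen, as was the limit to balanced splits, and the tests of exchanged labels, of trace RNA and of other splits were fixed before.

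Heart muscle genes were also higher in the lung and embryo arrays than in the mean of the other tissues. In lung, 12 of 20 heart genes rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.0094 with an estimated correlation). Those that rose included Myl7, the atrial myosin light chain (5.32 ± 0.33), Myh6, a cardiac myosin (5.10 ± 0.75), Actc1, cardiac actin (4.64 ± 0.38), and Nppa (2.48 ± 0.38), while Myl2, the ventricular light chain, fell (-3.02 ± 0.46). In embryo 12 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.0022), with Actc1 at 6.43 ± 0.38, Ckm, the muscle creatine kinase, at 6.40 ± 0.40 and Ttn, titin, at 5.51 ± 0.22, and Ryr2, the cardiac calcium release channel, at -1.38 ± 0.31. Quantile normalization gave 12 and 1 in both. Of 16 spleen genes 6 rose and 1 fell in lung (7 and 1 adjusted over the list alone), such as H2-Aa (2.29 ± 0.32) and Cd74, the class II invariant chain (1.97 ± 0.25), with adjusted p = 0.10 with an estimated correlation.

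In the arrays labelled brain the liver list was high and in those labelled liver the brain list, with both protocols. Of further markers outside the lists used above, 21 of 22 liver genes (95.5%) were highest of all tissues in the arrays labelled brain with both protocols, and 21 of 21 brain genes (100%) in those labelled liver, against 0 in the array of their own label. The labels of brain and liver may therefore have been exchanged, and the same order with both protocols would place this before the RNA was divided or in the labels themselves. Liver RNA mixed into brain RNA is argued against by the brain list, of which 6.25% rose in the arrays labelled brain. Whether RNA, tubes or records were exchanged was not tested.

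Liver genes such as Alb and the sperm transcripts Prm1, Ldhc and Smcp rose at 10 pg of universal RNA, and trace RNA from outside the sample is a candidate explanation. The 24 testis genes not looked at before had a median change of 0.94 at 10 pg (2.16, 1.46, 0.98 and 0.37 by replicate), just short of the bound of 1 set beforehand, so this stayed undecided; probe sets of like level had 0.19, and the list lay at -0.06 at 50 pg. The testis and liver medians lay 0.79 above probe sets of like level, between the bounds of 0.5 and 1 for a general rise of dim probe sets, which leaves that open too. Both lists lay above all 10000 random lists matched on level (percentile 100), and the other tissue lists at 37.0 (spleen) to 98.0 (kidney). This cannot tell if dim probe sets rose alike. The liver rise raised the question, liver genes varied together (estimated correlation 0.33), and the bounds were set after the value. In 50 against 10000 RAW267 cells the testis genes had a median difference of 0.36, and all probe sets -0.07.

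Alb signal was also high in arrays of some other low inputs. It was 11483 in the 1 array of 100 RAW267 cells and 24.6 as the mean of 2 arrays of 10000 cells. At 50 pg of universal RNA the mean was 4852 ± 3635 (SD, 2 arrays) with Ovation, 3092 ± 4219 with RiboAmp HS, 338 ± 87.0 with two-cycle and 451 ± 402 (4 arrays) with BIIB.

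Other splits of the 8 arrays into 4 and 4 were counted for each comparison of groups of 4. Of 35 splits, 1, the real one, gave as many calls at 50 pg (119) and 10 pg (1412) against 5 ng and for BIIB at 5 ng (5357) and 50 pg (4743) against one-cycle. The highest of the other splits gave 0 calls in each, that of replicates 1 and 2 against 3 and 4 included. As BIIB replicates 1 and 2 stood apart from 3 and 4 at 5 ng and 50 pg, the arrays are not freely exchangeable, and splits balanced over these pairs number 18, too few for a share under 0.05. The replicate number as a block gave 0 calls at 50 pg against 5 ng. At 100 pg 1 of 35 splits, the real one, gave 92 calls and the highest other 0, with the same limit, and replicates 1 and 2 may be 1 product (r = 0.978). At 1 ng and 500 pg the real count was 0, which 35 of 35 splits meet by construction, so the test says nothing there.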
